A study of Mus musculus with 13 samples.

How the data were processed

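RNA sequencing counts were analysed for 13 libraries of CD45-positive, CD49f-negative cells sorted from mouse epidermis. RNA was isolated with a column kit for small samples, and complementary DNA was made with the SMARTer Ultra Low Input kit, version 2, per the labels' protocols, and sequenced on a HiSeq 2500. The values analysed are raw read counts per gene, as deposited by the authors, without normalization. Reads were aligned with GSNAP and counted with featureCounts on mm10, per the submitters' processing notes, with Ensembl release 75 genes; versions, the strand setting and the treatment of reads with several matches were not given in the sources used here. The kit does not mark strand, so overlapping genes on opposite strands share reads, and assignment of reads shared by paralogs or pseudogenes can move the counts of those genes.

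The table held 38924 genes, of which 26434 had at least 1 count. Symbols were found for 37607 of the identifiers in the GENCODE names, and 1317 without one, which held 0.332 to 0.396% of counts per library, stayed in the analysis under their identifiers. Coordinates are those of the deposited table, counted from 1. Library totals were 13846981 to 25196458 counts. TMM factors lay between 0.918 and 1.03, except 1.246 in Cre-negative library 6. Values in CPM are counts scaled to a common library size by TMM, in the usual CPM unit, given as mean ± SD over libraries. No pair of libraries was a copy: the lowest chi-square per degree of freedom was 23.6 among 36 pairs of the same group and 54 among 42 pairs of different groups. Cre-positive and Cre-negative groups came from the genotype labels, and replicate numbers follow accession order, so they pair no samples. Sex was read from Xist against the Y-linked genes Ddx3y, Eif2s3y, Kdm5d and Uty.

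Genes were kept by filterByExpr (minimum count 10, minimum total 15), which left 14372. Differences between genotypes were tested with edgeR's quasi-likelihood test (edgeR 4.0.16, R 4.3.3), two-sided, with Benjamini-Hochberg adjustment and a threshold of 0.05; standard errors were derived from the fold change and the F statistic. The common biological coefficient of variation was 50.8%, and 45.7% with the title series in the fit. The main design had no covariate, since the labels name no batch; the numbering series of the titles entered as an alternative and is reported beside the main values because 1984 genes differed between series 51 and 48. Before the data were examined, 38 gene lists of cell type markers and pathways (494 symbols, 486 measured) were fixed, together with the main design, the alternatives and the rule for named genes. Symbols missing from the table were matched through RefSeq synonyms. Lists with at least 4 tested members were tested with camera (limma 3.58.1) on log2 CPM (prior count 2) with a preset correlation of 0.01; an estimated correlation and fry were alternatives. No gene was in more than 1 list. Adjustment over the list alone means Benjamini-Hochberg adjustment of edgeR's p-values within that list. Summed marker levels of 38 lists and of Ptprc and Itga6 (40 in all) were compared by exact permutation over the 1716 splits of 13 libraries into 7 and 6, and within title series over 525 arrangements; the smallest p these allow are 0.000583 and 0.0019. The same permutation of the mean log2 CPM of each list was added after seeing the data.

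The rule for named genes took Rnaseh2b, Rnaseh2a, Rnaseh2c, Ptprc and Itga6; up to 10 called genes per direction with a mean of at least 5 CPM in the higher group and a gene symbol that is not a clone name; and, per list, up to 4 members past the threshold over all genes, or the 2 most abundant where none passed. Genes named beyond it were chosen after their values were seen.

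Alternatives fixed beforehand were DESeq2 size factors, upper-quartile factors and library size alone as scaling, no filter and a filter of at least 50 counts in 6 libraries, the DESeq2 Wald test (DESeq2 1.42.0), limma-voom with quality weights, robust dispersion, title series or sex as a covariate, each title series alone, a threshold of 0.01, a 2-fold minimum, a prior count of 0.5 for marker levels, and leaving out each library. Title series with sex, leaving out jointly the libraries with high monocyte levels, with or without the one with a high Itga6 level, leaving out the latter with the title series in the fit, sex or library size alone for lists, and marker levels within title series were added after seeing the data. The median log2 change of all genes was -0.006 with TMM, -0.019 with DESeq2 size factors, 0.012 with upper-quartile factors and -0.067 with library size alone.

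The tests were tested on simulated data with the real means and library sizes. For the comparison without covariate (14185 genes), 32, 66, 94 and 98% of genes changed by 1, 2, 3 and 4 on the log2 scale were recovered, and 8 unchanged genes were called. With the title series as a covariate (14183 genes) the shares were 12, 64, 94 and 98%, and 3 unchanged genes were called. A shifted list was found by camera with either correlation and by fry (14159 genes, 36 lists), and 0 of the other lists were called. The simulated genes varied independently, so this does not show how often camera with the preset correlation calls lists of co-expressed genes by chance.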

Results

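RNA was sequenced from leukocytes of mouse epidermis, sorted as cells that carry the leukocyte antigen CD45 and lack CD49f, the integrin alpha 6 chain found on basal keratinocytes. Every library came from a homozygous floxed Rnaseh2b background. Rnaseh2b encodes a subunit of ribonuclease H2, the enzyme that starts the removal of ribonucleotides from DNA. In 7 libraries the keratin 14 Cre transgene, which drives recombination in keratinocytes, was present (Cre-positive), and in 6 it was absent (Cre-negative). The series concerns ribonucleotide excision repair in skin cancer, and its design asks how immune cells of the epidermis differ between the Cre genotypes. Totals ran from 15776926 to 25196458 counts in Cre-positive libraries and from 13846981 to 17882266 in Cre-negative ones, with 19110 to 20886 genes detected per library. Sample titles fell into a numbering series 51 (3 Cre-positive, 4 Cre-negative) and a series 48 (4 Cre-positive, 2 Cre-negative). Xist and Y-linked counts gave 9 male libraries (5 Cre-positive, 4 Cre-negative) and 4 female ones (2 in each group). Replicate numbers follow accession order, and since no label states that the libraries came from separate animals, p-values measure the spread between these samples, part of which may be technical.

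Rnaseh2b itself, at chromosome 14, 62292589 to 62372992 (mm10; ENSMUSG00000021932), was at 12.9 ± 4.09 CPM (SD, n = 7) in Cre-positive libraries and 13.0 ± 4.79 (n = 6) in Cre-negative ones, a log2 fold change of -0.01 (SE 0.26, adjusted p = 0.991, edgeR). Counts over the whole gene include exons outside the floxed part, and keratin 14 Cre acts in keratinocytes rather than in leukocytes, so this value does not check the genotype labels. The other subunits of the enzyme were close as well, Rnaseh2a at 42.6 ± 10.3 against 41.3 ± 8.17 CPM and Rnaseh2c at 32.0 ± 12.7 against 29.9 ± 10.7 CPM. None of the 5 measured ribonuclease H and topoisomerase 1 genes passed over all genes or adjusted over the list alone, and their list test gave an adjusted p = 0.727. Ptprc, which encodes CD45, stood at 1048 ± 292 against 1272 ± 379 CPM (adjusted p = 0.652). Itga6, which encodes CD49f, stood at 15.4 ± 7.66 against 37.3 ± 54.1 CPM (adjusted p = 0.483), and 1 library, Cre-negative 6, reached 147 CPM. T cell genes were abundant in both groups, with Cd3e, a chain of the T cell receptor complex, at 11544 ± 1646 against 10990 ± 2242 CPM and Cd3g at 10119 ± 1143 against 8737 ± 1675 CPM.

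Between the Cre genotypes, 6 of 14372 genes passed an adjusted p of 0.05, with Kirrel3, Kirrel3os, Cd160 and Myot lower and Fcgrt and BC117090 higher in Cre-positive libraries. Kirrel3 (chromosome 9, 34486126 to 35036716), an adhesion molecule of the immunoglobulin superfamily, fell from 14.96 ± 11.9 CPM (SD, n = 6) to 0.386 ± 0.275 (n = 7), a log2 change of -5.26 (SE 0.64, adjusted p = 0.0097). Kirrel3os (chromosome 9, 34918233 to 34929509), which lies on the opposite strand within Kirrel3, fell from 7.72 ± 2.68 to 0.743 ± 0.44 CPM (log2 -3.37, SE 0.45, adjusted p = 0.0148). Because the library kit does not mark strand, reads from any stretch where exons of this pair overlap cannot be told apart. The share of such reads was not measured. Cd160 (chromosome 3, 96798763 to 96829351), a receptor of cytotoxic lymphocytes, fell from 163 ± 40.7 to 71.9 ± 11.9 CPM (log2 -1.18, SE 0.18, adjusted p = 0.0233). Myot (chromosome 18, 44334074 to 44355724), which encodes the sarcomere protein myotilin, fell from 14.3 ± 8.34 to 0.983 ± 0.954 CPM (log2 -3.86, SE 0.63, adjusted p = 0.0492). Fcgrt (chromosome 7, 45092993 to 45103822), which encodes the heavy chain of the neonatal Fc receptor, rose from 38.2 ± 9.32 to 93.5 ± 17.1 CPM (log2 1.29, SE 0.19, adjusted p = 0.0233). BC117090 (chromosome 16, 36321665 to 36334332), a member of the stefin A cluster whose near-identical neighbours make its count uncertain, rose from 0.104 ± 0.0848 to 2.36 ± 1.85 CPM (log2 4.43, SE 0.66, adjusted p = 0.0233). The DESeq2 Wald test on the same 14372 genes called 248, 105 higher and 143 lower, among them all 6. At an unadjusted p under 0.05 edgeR gave 1571 genes, 788 higher and 783 lower. Without Cre-positive library 6 no gene passed (edgeR; 1246 unadjusted), and without Cre-negative library 5 there were 13. Kirrel3 and Kirrel3os lost their calls in that first omission alone (highest adjusted p 0.0552 and 0.0578), whereas Cd160, Fcgrt, BC117090 and Myot lost theirs in 10, 9, 7 and 11 of the 13 omissions, at adjusted p of up to 0.0897, 0.0881, 0.0897 and 0.162.

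**Figure D1:**
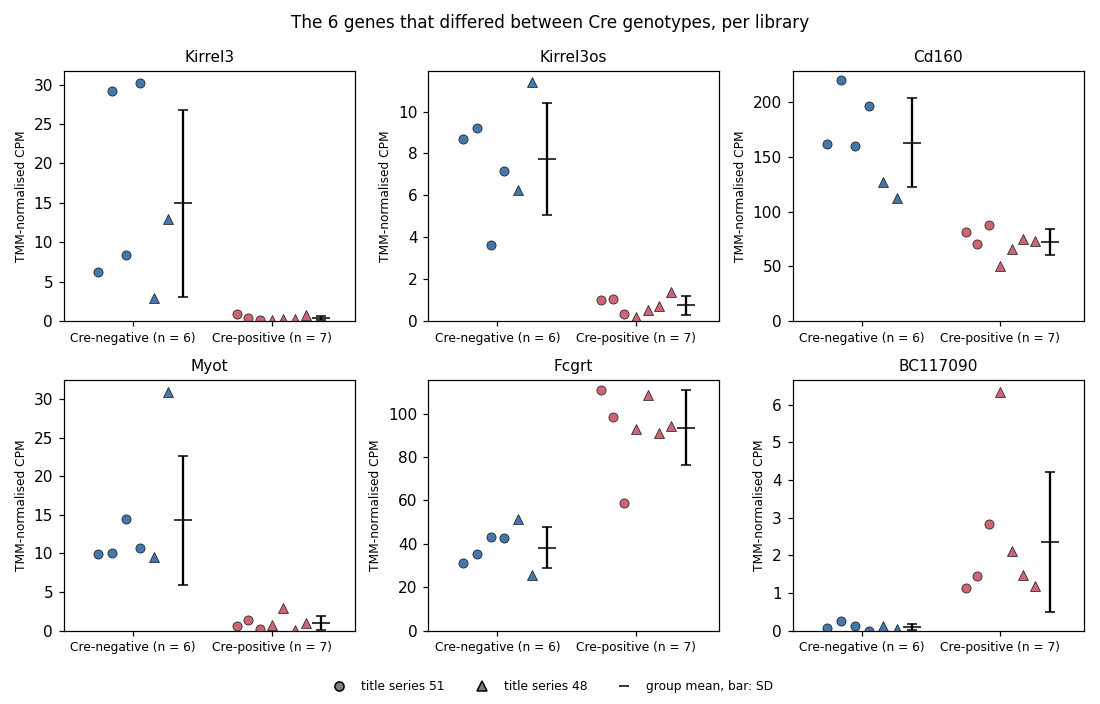
TMM-normalised CPM (vertical axis, from 0) of the 6 genes that passed in the comparison of Cre genotypes, 1 point per library, with circles for title series 51, triangles for series 48, and the group mean with its SD as a bar (n = 6 Cre-negative, n = 7 Cre-positive). Kirrel3 lay between 2.87 and 30.2 CPM in Cre-negative libraries and at 0.844 CPM or less in Cre-positive ones.

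With the title series held constant, CD8 T cell genes joined the called set: Cd8a and Cd8b1, the chains of the CD8 co-receptor, were higher in Cre-positive libraries. Cd8a (chromosome 6, 71373427 to 71379171) stood at 57.4 ± 30.0 against 13.5 ± 10.7 CPM, and Cd8b1 (chromosome 6, 71322836 to 71337477) at 77.3 ± 33.8 against 16.2 ± 11.4 CPM. Their log2 changes in this fit were 2.43 (SE 0.38, adjusted p = 0.0338) and 2.77 (SE 0.41, adjusted p = 0.0259). Also higher were AW112010 (chromosome 19, 11047617 to 11050566; 306 ± 109 against 133 ± 49.6 CPM) and the interferon-induced Ifi27l2a (chromosome 12, 103442167 to 103443680; 126 ± 89.5 against 27.7 ± 16.5 CPM). So were Cdkn2c, an inhibitor of cyclin-dependent kinases (chromosome 4, 109660876 to 109667189; log2 0.87), and Actg2, a smooth muscle actin (chromosome 6, 83512905 to 83536265; log2 3.40). Lower genes included Il34, a ligand of the Csf1 receptor made by keratinocytes (chromosome 8, 110741829 to 110805924), at 13.1 ± 5.71 against 47.9 ± 33.2 CPM. Hpgd, which breaks down prostaglandins (chromosome 8, 56294552 to 56321046), was at 6.09 ± 3.77 against 69.6 ± 80.7 CPM. The remaining lower genes were Lrp4, Cmah, Wnk2, Hdac9 and Foxn3, with log2 changes of -2.16, -1.27, -3.40, -1.60 and -1.07. This fit called 19 genes, 8 higher and 11 lower, among them all 6 of the fit without the covariate (1948 at an unadjusted p under 0.05). The 13 added genes, BC117090, and the list members named below that passed adjusted over the list alone were chosen after their values were seen, unless the rule fixed beforehand also names them. Without Cre-negative library 6, which had the lowest Cd8b1 level (1.45 CPM) and the highest Itga6 level, the same fit called 2 genes, Cd160 and Cd8b1 (adjusted p = 0.00971). Cd8a then had an adjusted p = 0.0615, and none of the other added genes kept its call. Within series 51 alone and series 48 alone, edgeR called 0 genes (1600 and 1420 unadjusted).

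Of 36 gene lists with enough tested members, 17 stood apart by camera with a preset correlation, 14 higher and 3 lower in Cre-positive libraries, both without and with the title series in the fit. None of the 17 held with an estimated correlation (3 lists unadjusted). The directional test fry called 2 lists (12 unadjusted), stress keratinocyte (adjusted p = 0.0369) and melanocyte genes (adjusted p = 0.0497). With the title series in the fit neither of the 2 passed by fry (adjusted p = 0.0551 for each). An exact permutation of each list's mean log2 CPM, two-sided over all 1716 splits, called 1 list after adjustment (12 unadjusted), and permutation within title series called 7 (13 unadjusted). Cre-positive libraries 1 and 2 had the highest monocyte and macrophage means. Cre-negative library 6 had the highest Itga6 level and the highest basal keratinocyte mean (8.36 log2 CPM). Its Cd3e was the lowest (7328 CPM), while its Ptprc (1290 CPM) was not. Its means were the lowest of the 13 libraries for most lists called higher, among them type I interferon, MHC class I and alpha-beta T cell genes. Those for monocyte, stress keratinocyte and melanocyte genes were not the lowest. Without Cre-positive libraries 1 and 2, 13 of the 17 lists kept their calls, and without these and Cre-negative library 6, 8 did. Over all genes tested, Cd160 was the only list member past the threshold without the covariate. Adjusted over the list alone, 84 members passed, of which 59 also passed with the title series in the fit and 36 without Cre-positive libraries 1 and 2. In each of the 13 single omissions, and with the title series, 26 kept that call: Dct, Tyrp1, Pmel, Mlana, Tyr, Krt6a, Krt6b, Krt16, Sprr1b, Cd8a, Cd8b1, Cd160, Klrb1c, Ifng, Prf1, Tnfrsf9, Il1r1, Irgm1, Il34, Il4, Scd1, Cd9, Fabp5, Kit, Ltf and Mmp9. Of these 26, Kit and Prf1 lost it without both Cre-positive libraries 1 and 2. Tyr, Il4 and Kit lost it without Cre-negative library 6 with the title series in the fit. The other 58 members lost it in at least 1 omission.

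**Figure D2:**
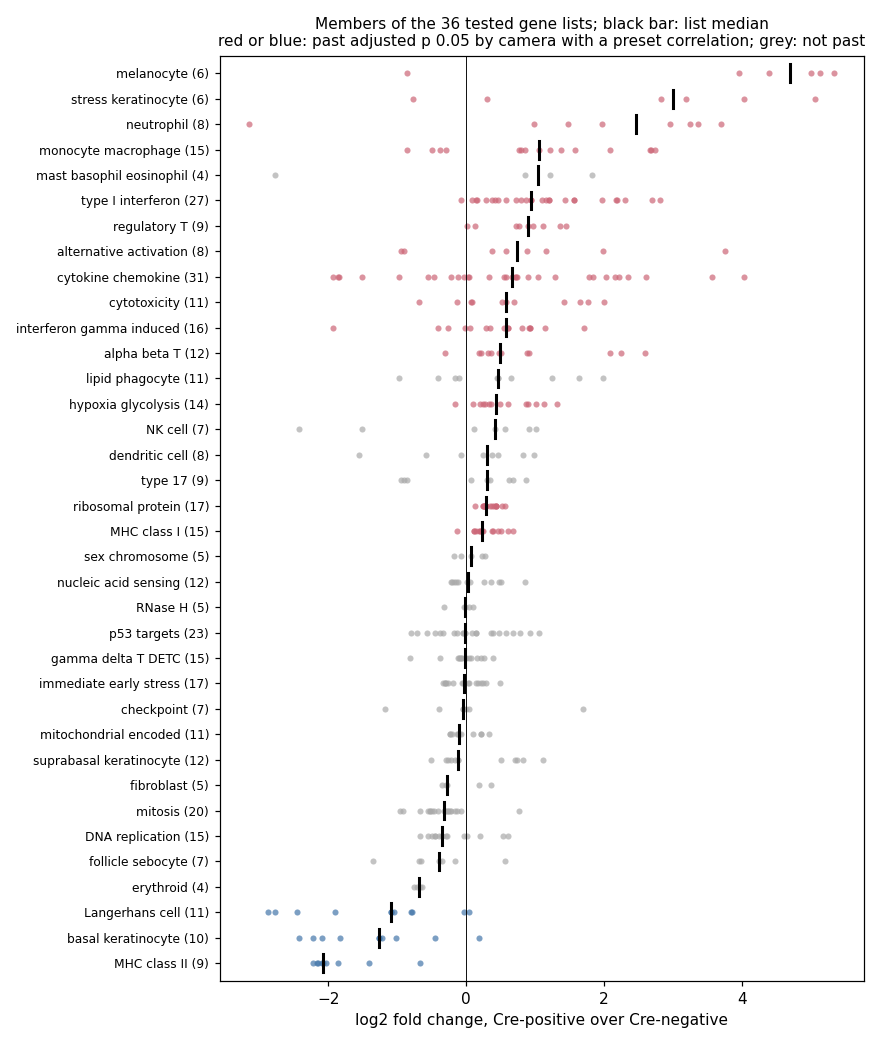
Log2 fold changes of Cre-positive over Cre-negative libraries (horizontal axis) for the tested members of 36 gene lists (vertical axis, number of members in brackets), 1 point per gene, with the list median as a black bar. Red and blue mark the 14 higher and 3 lower lists by camera with a preset correlation, grey the others; medians reached 4.70 for melanocyte genes and -2.08 for MHC class II genes.

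Genes of melanocytes and of stressed keratinocytes had the highest list medians. Krt6a, a keratin induced on wounding, was at 63.5 ± 43.4 CPM (SD, n = 7) in Cre-positive libraries against 8.97 ± 5.63 (n = 6), Krt16 at 36 ± 30.3 against 3.93 ± 2.96 CPM, and Krt6b at 39.55 ± 49.7 against 1.17 ± 1.55 CPM. Of 6 tested stress keratinocyte genes, 4 (those 3 and Sprr1b) rose adjusted over the list alone and 0 over all genes, with a median log2 change of 3.005 and Krt17 in the other direction at -0.77. The list's adjusted p was 4.98e-06, and the adjusted p = 0.303 with an estimated correlation. Its mean was higher in all 7 Cre-positive libraries than in any Cre-negative one (difference 2.43, exact permutation p = 0.000583, the smallest that 1716 splits can give, adjusted p = 0.021). The summed level of all 12 measured genes of this list, of which Krt17 was the most abundant tested one, did not differ by test (398 against 322 CPM as geometric means, 1.24-fold, exact permutation p = 0.713), and its log2 difference in series 48 was -0.29. For the list mean within title series the exact p was 0.0019, the smallest of 525 arrangements (adjusted p = 0.0342), with differences of 2.605 in series 51 and 2.22 in series 48. Of the melanocyte genes, Dct and Tyrp1, enzymes of pigment synthesis, were at 47.9 ± 53.6 against 3.08 ± 2.85 CPM and 41.2 ± 64.5 against 1.17 ± 1.28 CPM. These and Pmel, Mlana and Tyr rose adjusted over the list alone, whereas Mitf, the transcription factor of the lineage, was lower (2.39 ± 1.01 against 4.36 ± 1.53 CPM) but lost that call with the title series (adjusted p = 0.0704 over the list alone) and in 7 of 13 omissions. Over all genes 0 of the 6 passed. The list's adjusted p was 5.35e-06, and the adjusted p = 0.303 with an estimated correlation. Its mean differed by 3.22 (exact permutation p = 0.00291, adjusted p = 0.0524; within title series exact p = 0.00381, adjusted p = 0.0457), by 1.685 in series 51 and 4.41 in series 48. The summed level of its 6 genes, 88.5 against 9.81 CPM as geometric means, was the only one of 40 marker levels past adjustment (9.02-fold, exact permutation p = 0.00117, adjusted p = 0.0468), and within title series its adjusted p was 0.076.

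**Figure D3:**
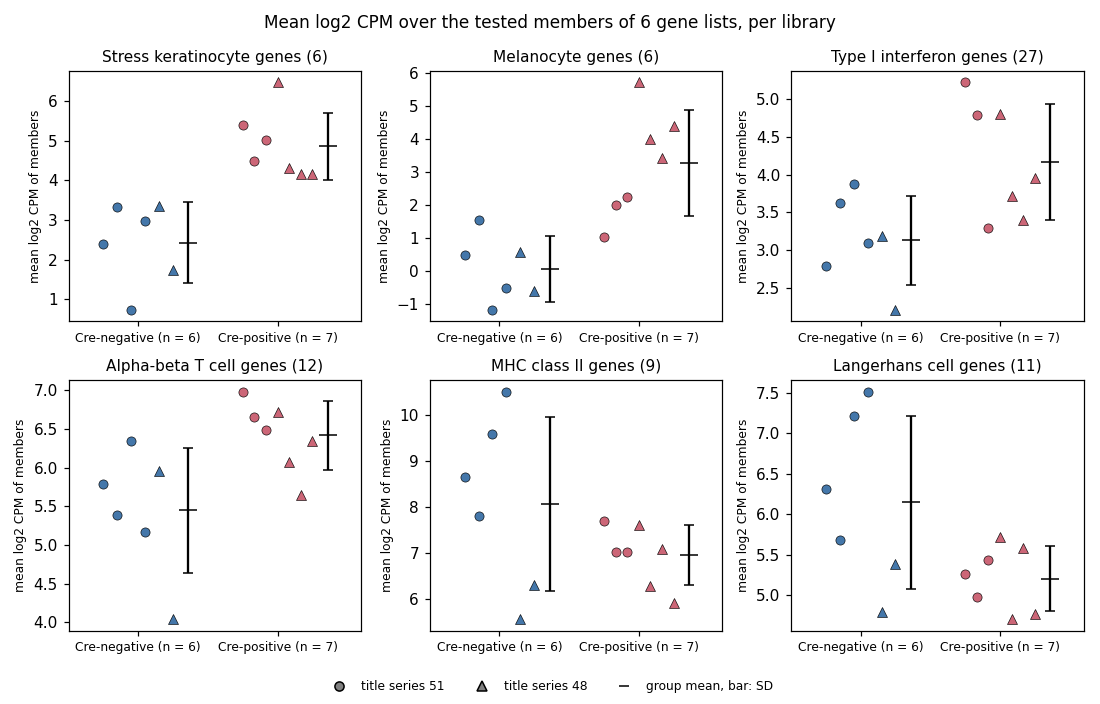
Mean log2 CPM over the tested members of 6 gene lists (vertical axis), 1 point per library, circles for title series 51 and triangles for series 48, with the group mean and its SD as a bar (n = 6 Cre-negative, n = 7 Cre-positive). All 7 Cre-positive libraries lay above the 6 Cre-negative ones for stress keratinocyte genes, and the MHC class II difference was -1.89 in series 51 and 0.79 in series 48.

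Of the other epidermal lists, basal keratinocyte genes stood lower and the suprabasal and follicle lists did not pass. Krt15, a keratin of basal and follicle stem cells, was at 496 ± 372 against 2674 ± 2676 CPM, while Krt14 was at 1476 ± 1033 against 1301 ± 1257 CPM. Krt15, Col17a1 and Dst fell adjusted over the list of 10 basal keratinocyte genes alone (0 over all genes; median log2 -1.27, adjusted p = 0.0158, and the adjusted p = 0.751 with an estimated correlation). That call was lost without Cre-positive library 1 or 2 or without Cre-negative library 5 or 6 (highest adjusted p 0.272). The 3 single-gene calls were kept with the title series (adjusted p = 0.0402 over the list alone), but were lost with sex as a covariate and in 9 of 13 omissions. The median was -0.23 without Cre-negative library 6, -0.93 without both of those Cre-positive libraries (adjusted p = 0.643), and 0.14, in the other direction, without all 3 (adjusted p = 0.516). The 12 suprabasal genes, led by Krtdap (862 ± 775 against 1032 ± 996 CPM) and Lgals7, gave an adjusted p = 0.875, a median of -0.12 and a mean of 0.18. Scd1, a fatty acid desaturase of sebocytes, fell adjusted over the follicle and sebocyte list alone (23.9 ± 8.61 against 61.1 ± 20.2 CPM), and Krt79 stood at 44.3 ± 35.2 against 58.1 ± 55.5 CPM (list adjusted p = 0.26, and 0.0331 without Cre-negative library 3). Fibroblast genes, with Sparc at 137 ± 80.2 against 106 ± 86.9 CPM, gave an adjusted p = 0.756, and so did the erythroid genes, with Hba-a1 at 2.22 ± 1.52 against 3.46 ± 3.57 CPM. Of the endothelial list only 3 genes were tested, too few for a list test, and Pecam1 stood at 6.85 ± 2.52 against 4.06 ± 3.07 CPM.

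Type I interferon genes stood higher in Cre-positive libraries. The antiviral genes Ifit1 (20.7 ± 14.6 CPM, n = 7, against 5.27 ± 4.25, n = 6), Rsad2 (12.7 ± 12.7 against 1.80 ± 2.00) and Zbp1 (34.3 ± 15.2 against 15.3 ± 6.03) were among 9 of 27 that rose adjusted over the list alone. None of the 27 passed over all genes, but Ifi27l2a did with the title series in the fit. Of the most abundant members, Bst2 was at 366 ± 78.5 against 281 ± 79.1 CPM and Stat1 at 276 ± 49.7 against 207 ± 69.9 CPM. The median log2 change was 0.94, 26 of 27 genes were positive, and the list's adjusted p was 6.06e-09, and the adjusted p = 0.303 with an estimated correlation. The list mean differed by 1.04 (exact permutation p = 0.0245, adjusted p = 0.098), and within title series by 1.09 and 1.27 (exact p = 0.0152, adjusted p = 0.0684). Without Cre-positive libraries 1 and 2, the monocyte-rich ones, the median was 0.45 (adjusted p = 0.000392) and without Cre-negative library 6 as well it was 0.26 (adjusted p = 0.00595), with 0 members past adjusted over the list alone in either case. Leaving out Cre-negative library 1 or 4 also ended the call of each of the 9, all of which passed with the title series.

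Genes of antigen presentation by MHC class I stood higher. B2m, the shared light chain, stood at 7868 ± 1228 against 5549 ± 1113 CPM (log2 0.50), and B2m, H2-K1, H2-Q6 and H2-Q7 rose adjusted over the list of 15 alone (0 over all genes), also with the title series, but they kept that call in only 5, 2, 5 and 2 of the 13 omissions. H2-D1 stood at 3619 ± 2532 against 3264 ± 2084 CPM, and counts of the H2 genes, like those of the Krt6 pair, depend on how reads shared by close paralogs were assigned. Camera gave an adjusted p = 0.000297, and the adjusted p = 0.338 with an estimated correlation; the exact permutation p of its mean was 0.046 (adjusted p = 0.138). Within title series that p was 0.0019, the smallest possible (adjusted p = 0.0342). Without Cre-negative library 6 the median went from 0.23 to 0.14 (adjusted p = 0.00666). Without Cre-positive libraries 1 and 2 it was also 0.14, with 0 members past adjusted over the list alone (adjusted p = 0.0278), and without Cre-negative library 6 as well the list lost its call (adjusted p = 0.204). Of 16 genes induced by interferon gamma, the GTPase Irgm1 rose adjusted over the list alone (113 ± 37.5 against 51.4 ± 15.3 CPM) and Ciita, the activator of MHC class II genes, was lower (4.21 ± 1.36 against 16.2 ± 13.97 CPM), with 0 over all genes. The call of Ciita was lost with the title series (adjusted p = 0.145 over the list alone) and without Cre-positive library 2, 3 or 7 or Cre-negative library 3 or 4. Igtp, another GTPase, stood at 96.1 ± 35.7 against 63.0 ± 11.3 CPM. Camera gave an adjusted p = 0.00435, and the adjusted p = 0.367 with an estimated correlation; without Cre-negative library 4 it was 0.056, without Cre-positive libraries 1 and 2 and Cre-negative library 6 it was 0.204, and without Cre-negative library 6 and with the title series it was 0.0921. Nucleic acid sensors, with Tmem173 (STING) at 93.6 ± 45.2 against 101 ± 37.1 CPM and Samhd1 at 69.9 ± 22.5 against 50.3 ± 17.2 CPM, gave an adjusted p = 0.645.

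Langerhans cell and MHC class II genes stood lower in Cre-positive libraries, with a wide spread among the Cre-negative ones. Cd207, which encodes langerin, was at 68.5 ± 38.0 CPM (n = 7) against 471 ± 538 (n = 6), and Csf1r and Adgre1 were at 40.1 ± 15.8 against 221 ± 227 CPM and 27.6 ± 15.2 against 204 ± 246 CPM. Of 11 Langerhans cell genes, 9 fell adjusted over the list alone and 0 over all genes (median log2 -1.09, adjusted p = 0.000363, and the adjusted p = 0.303 with an estimated correlation), whereas the adhesion gene Cdh1 stood at 430 ± 105 against 439 ± 118 CPM. Cd74, the invariant chain, was at 2944 ± 1046 against 12448 ± 13341 CPM and H2-Aa at 1085 ± 444 against 4631 ± 5158 CPM. Of 9 MHC class II genes, 7 fell adjusted over the list alone and 0 over all genes (median -2.08, adjusted p = 0.00184, and the adjusted p = 0.522 with an estimated correlation). With the title series as a covariate, no gene of either list passed adjusted over the list alone, and the medians were -1.02 and -1.08. By exact permutation the list means did not pass (Langerhans p = 0.0513, within title series 0.116; MHC class II p = 0.171, within title series 0.389). The MHC class II difference was -1.89 in series 51 and 0.79 in series 48, the Langerhans difference -1.46 and 0.10. Without Cre-negative library 4 the MHC class II list lost its call (median -1.37, adjusted p = 0.0651) and 0 genes of either list fell adjusted over the list alone. With title series and sex as covariates the MHC class II call was also lost (adjusted p = 0.0504). Dendritic cell genes gave an adjusted p = 0.727, with Batf3 lower adjusted over the list alone (4.02 ± 2.15 against 11.9 ± 6.12 CPM; not without Cre-negative library 4), Ccr7 at 150 ± 88.4 against 84.5 ± 30.9 CPM and Xcr1 at 22.3 ± 6.81 against 18.9 ± 5.35 CPM.

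Among T cells, no difference was detected in genes of gamma-delta dendritic epidermal T cells, while several alpha-beta T cell genes stood higher in Cre-positive libraries. The 15 genes of the gamma-delta list had a median log2 change of -0.019 and an adjusted p = 0.912, with 0 past either adjustment. They include Cd3e and Cd3g, which alpha-beta T cells also express, so the list does not isolate the gamma-delta lineage. Of 12 alpha-beta T cell genes, Cd8a, Cd8b1, Lef1 and Trbc1 rose adjusted over the list alone, 0 over all genes, and Cd8a and Cd8b1 over all genes with the title series in the fit. Lef1 lost its call without Cre-positive library 4 or Cre-negative library 4 or 6, and Trbc1 in 8 of 13 omissions. Of the abundant members, Trbc2 was at 486 ± 150 against 391 ± 84.0 CPM and Tcf7 at 236 ± 53.6 against 290 ± 73.7 CPM. For the list the adjusted p was 5.14e-05, and the adjusted p = 0.303 with an estimated correlation. Its mean differed by 0.97 (exact permutation p = 0.0152, adjusted p = 0.0972; within title series exact p = 0.00952, adjusted p = 0.049). Without Cre-positive libraries 1 and 2 and Cre-negative library 6 the camera call was lost (adjusted p = 0.0667), and without Cre-negative library 5 the median went from 0.49 to 0.85. Tnfrsf9 (4-1BB), a costimulatory receptor, was at 1111 ± 294 against 515 ± 147 CPM, and it rose with Tnfrsf4 and Tnfrsf18 adjusted over the regulatory T cell list of 9 alone (0 over all genes). Tnfrsf4 and Tnfrsf18 kept that call in 4 of 13 omissions, and without Cre-positive library 1 Tnfrsf9 alone passed. Those receptors also mark activated T cells; Foxp3, the factor of the regulatory lineage, stood at 14.3 ± 9.03 against 8.63 ± 8.92 CPM and Icos at 672 ± 295 against 359 ± 356 CPM. The list's adjusted p was 1.24e-05, and the adjusted p = 0.303 with an estimated correlation (exact permutation of its mean p = 0.0198, adjusted p = 0.0972). Type 17 genes gave an adjusted p = 0.563, with Il1r1 lower adjusted over the list alone (14.04 ± 3.49 against 25.6 ± 6.01 CPM) and Ccr6 at 268 ± 119 against 147 ± 94.6 CPM.

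Genes of cytotoxic effectors differed in both directions. Ifng, which encodes interferon gamma, rose from 6.51 ± 3.47 to 22.1 ± 7.54 CPM adjusted over the list of 11 alone, as did the granule proteoglycan Srgn, while perforin, Prf1, fell from 1957 ± 511 to 1215 ± 283 CPM, with 0 over all genes. Srgn lost its call in 7 of 13 omissions. Nkg7 and Ctsw, the most abundant members, stood at 7102 ± 846 against 6760 ± 1010 CPM and 3107 ± 209 against 2942 ± 894 CPM. For the list the adjusted p was 0.00709, and the adjusted p = 0.377 with an estimated correlation; without Cre-negative library 6 it was 0.0652, and without Cre-positive libraries 1 and 2 it was 0.121. Klrb1c (NK1.1), a receptor of natural killer cells, fell from 140 ± 54.7 to 48.8 ± 29.7 CPM adjusted over its list alone. The NK cell list as a whole gave an adjusted p = 0.912, with a median of 0.42 and a mean of -0.13, and Klrd1 at 691 ± 266 against 638 ± 251 CPM. Of the checkpoint receptors Cd160 passed both adjustments, and the list gave an adjusted p = 0.659 with a median of -0.05 and a mean near 0 (0.008).

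Monocyte, alternative activation and neutrophil genes stood higher as lists in Cre-positive libraries, and the first 2 of these calls ended in several omissions. Lyz2, lysozyme, was at 320 ± 451 against 107 ± 65.4 CPM and Apoe at 87.9 ± 39.7 against 159 ± 99.1 CPM. The 15 monocyte and macrophage genes had a median log2 change of 1.055, with 0 past either adjustment (adjusted p = 0.0173, and the adjusted p = 0.392 with an estimated correlation). The list mean was highest in Cre-positive libraries 1 and 2 (5.10 and 4.87), which also had low basal keratinocyte means (2.56 and 3.12), and without these libraries the list's adjusted p was 0.46. Each of Cre-positive libraries 1 and 2 and Cre-negative libraries 1 and 5 ended that call when left out (highest adjusted p 0.105). The alternative activation list, with Il4ra at 372 ± 245 against 286 ± 310 CPM and Mgl2 at 11.3 ± 5.91 against 21.1 ± 14.02 CPM, had 0 members past either adjustment (adjusted p = 0.0341, and the adjusted p = 0.303 with an estimated correlation). It lost its call without Cre-positive library 1, 2 or 7 or Cre-negative library 1, 2 or 6 (highest adjusted p 0.116), and without both Cre-positive libraries 1 and 2 its adjusted p was 0.289. With sex as a covariate it was 0.0511, with title series and sex 0.0628, and without Cre-negative library 6 and with the title series 0.133. The difference of its mean was -0.32 in females and 1.48 in males (exact permutation p of the difference between the sexes 0.00794, adjusted over 36 lists 0.286). Its median of 0.73 was 1.20 without Cre-negative library 4. Of 8 neutrophil genes, S100a8 (33.8 ± 45.7 against 4.33 ± 5.12 CPM), S100a9, Trem1 and Ltf rose adjusted over the list alone, and the gelatinase Mmp9, also made by Langerhans cells, fell (13.6 ± 5.53 against 121 ± 135 CPM), with 0 over all genes. The list's median was 2.47 (adjusted p = 0.000839, and the adjusted p = 0.303 with an estimated correlation), but its summed level, carried by Mmp9, was 60.6 against 80.5 CPM. Among single omissions, S100a9 lost its call without Cre-positive library 1, S100a8 in 5 of 13 and Trem1 in 6. S100a8 reached 123 and 65.4 CPM in Cre-positive libraries 1 and 2; without them the neutrophil median was 0.97 with 1 member higher adjusted over the list alone (adjusted p = 0.0496), and without Cre-negative library 6 as well it was 0.74 (adjusted p = 0.204).

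Genes of several secreted factors passed adjusted over their list alone. Of 31 cytokine and chemokine genes, the macrophage inflammatory proteins Ccl3 and Ccl4 (67.6 ± 84.7 against 13.3 ± 10.1 CPM), Cxcl3, Il4 and Osm rose adjusted over the list alone, Il34 and Il18 (6.995 ± 4.55 against 26.9 ± 29.7 CPM) fell, and 0 passed over all genes. The call of Il18 was lost with the title series (adjusted p = 0.224 over the list alone), those of Il18 and Cxcl3 with sex as a covariate, and Ccl3, Ccl4, Cxcl3, Osm and Il18 kept theirs in 3 to 6 of 13 omissions. Areg, a growth factor for epithelium, stood at 313 ± 279 against 91.3 ± 75.7 CPM and Ccl5 at 199 ± 78.7 against 96.1 ± 73.5 CPM. The list's adjusted p was 0.000839, and the adjusted p = 0.303 with an estimated correlation. Without Cre-positive library 1, or libraries 1 and 2, the median went from 0.67 to 0.26 (adjusted p = 0.00363 and 0.00883), and without Cre-negative library 6 as well the call was lost (median 0.015, adjusted p = 0.182). It was also lost without Cre-negative library 6 alone with the title series in the fit (median 0.044, adjusted p = 0.133). Mast cell, basophil and eosinophil genes gave an adjusted p = 0.563, with Kit higher (97.4 ± 41.4 against 41.7 ± 19.6 CPM) and Siglecf lower adjusted over the list alone, the latter lost with the title series (adjusted p = 0.159 over the list alone), with sex and in 10 of 13 omissions, and Il1rl1 at 14.5 ± 5.72 against 8.002 ± 10.4 CPM. B cell genes had 3 tested members, too few for a list test; Cd79a and Cd79b (9.22 ± 4.65 against 3.14 ± 3.10 CPM) rose adjusted over the list alone (kept in 9 and 6 of 13 omissions), and Ighm stood at 401 ± 108 against 497 ± 60.8 CPM. The lipid-handling phagocyte list gave an adjusted p = 0.671. In it Fabp5 (53.5 ± 37.3 against 17.1 ± 3.83 CPM) and Lgals3 (1204 ± 177 against 874 ± 204 CPM) rose and Cd9 (601 ± 196 against 1183 ± 465 CPM) and Abcg1 fell adjusted over the list alone, with 0 over all genes; Lgals3 and Abcg1 kept that call in 4 and 6 of 13 omissions.

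Lists of DNA damage and proliferation genes did not pass with all libraries, although most mitosis and DNA replication genes had negative log2 changes. The 23 tested p53 targets had 11 positive and 12 negative log2 changes, a median of -0.015 and an adjusted p = 0.645, with Cdkn1a (p21) at 820.0 ± 564 against 431 ± 341 CPM and Btg2 at 915 ± 325 against 1008 ± 468 CPM. Of 20 mitosis genes 19 had negative log2 changes (median -0.32, adjusted p = 0.412), with Top2a at 86.8 ± 55.5 against 104 ± 82.2 CPM and Cenpa, the exception, at 93.5 ± 54.7 against 54.7 ± 29.8 CPM. Of 15 DNA replication genes 11 were negative (median -0.35, adjusted p = 0.449), with Rrm1 at 338 ± 224 against 233 ± 154 CPM and Pcna at 115 ± 43.4 against 100.1 ± 22.5 CPM. No member of these lists passed either adjustment. Without Cre-negative library 4 both lists were lower by camera, mitosis genes with a median of -0.49 (adjusted p = 0.00131) and DNA replication genes with a median of -0.48 (adjusted p = 0.0195).

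Ribosomal protein genes stood higher: all 17 log2 changes were positive, the median was 0.28, and Rps4x (387 ± 41.5 against 299 ± 49.3 CPM), Rpl5, Rpl18, Rps6 and Rps8 passed adjusted over the list alone, with 0 over all genes. None of these 5 passed with the title series (adjusted p = 0.0664 over the list alone) or with sex as a covariate, and each kept its call in 2 of 13 omissions, those of Cre-positive library 3 and Cre-negative library 5. The abundant Rps3 and Rpl32 stood at 3051 ± 440 against 2517 ± 623 CPM and 2311 ± 405 against 1960 ± 338 CPM, and counts in this family depend on reads shared with processed pseudogenes. The list's adjusted p was 6.62e-07, and the adjusted p = 0.303 with an estimated correlation (exact permutation of its mean p = 0.00583, adjusted p = 0.07; within title series adjusted p = 0.049). Of 14 hypoxia and glycolysis genes, 13 were positive and 0 passed either adjustment, with Aldoa at 2393 ± 157 against 1984 ± 451 CPM and Ldha at 1242 ± 132 against 963 ± 228 CPM. Its adjusted p was 0.000181, and the adjusted p = 0.303 with an estimated correlation (median 0.43; within title series adjusted exact p = 0.049). Without Cre-negative library 6 and with the title series in the fit, that call was lost (median 0.13, adjusted p = 0.127). Immediate early and heat shock genes gave an adjusted p = 0.645, with Fos at 1908 ± 966 against 2371 ± 1314 CPM and Zfp36 at 468 ± 177 against 589 ± 381 CPM. Genes of the mitochondrial genome gave an adjusted p = 0.931, with mt-Cytb at 3489 ± 1708 against 3274 ± 1265 CPM and mt-Co1 at 3387 ± 1430 against 2704 ± 1063 CPM. In these last lists the median (-0.031 and -0.10) and the mean (-0.012 and -0.025) were negative while the test pointed up. Without Cre-negative library 6 and with the title series in the fit, immediate early genes were lower by camera (median -0.56, adjusted p = 0.000139, 6 members lower adjusted over the list alone); in the other settings tried the adjusted p was 0.127 or more. The sex-linked genes, with Ddx3y at 89.0 ± 63.9 against 100.2 ± 79.8 CPM and Xist at 77.8 ± 134 against 74.1 ± 111 CPM, gave an adjusted p = 0.906.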

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

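The tests of explanations and the 100 regroupings of the libraries were chosen after the results they bear on had been seen. Library values far from the rest of their group were looked for in 390 combinations of a named gene or list mean and a group, by Dixon's gap ratio; 13 stood apart, where chance gives about 1 in 20, or 19.5, and 10 of them were in Cre-negative library 6. That library was lowest for Rnaseh2c (gap ratio 0.775; log2 CPM 3.33, next 4.93), Bst2 (0.729; 7.06, next 8.12), B2m (0.701; 11.76, next 12.39), Pcna (0.806; 5.82, next 6.69) and Cxcl10 (0.726; -1.92, next 2.09). It was also lowest for Srgn (0.769; 9.46, next 10.37), Mitf (0.69; 0.82, next 2.11), Rpl18 (0.733; 5.59, next 6.54) and the ribonuclease H list mean (0.735; 4.26, next 4.83), and highest for Myot (0.647; 4.95, next 3.87). Cre-positive library 3 was lowest for Fcgrt (0.683; 5.88, next 6.51). Cre-negative library 5 was highest for Tnfrsf18 (0.656; 8.65, next 7.65) and Ltf (0.672; 0.71, next -1.92).

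Effects were also compared between sexes and title series. By edgeR, 0 genes had a Cre effect that differed between the sexes (393 unadjusted) and 0 one that differed between the title series (1081 unadjusted). No list mean passed adjustment for either interaction; unadjusted, 1 list differed between title series, MHC class II, and 1 between sexes, alternative activation (exact p = 0.00794).

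By list mean, melanocyte and stress keratinocyte genes were higher in Cre-positive libraries, although a CD45 gate should remove both cell types and the summed stress keratinocyte level did not differ by test (1.24-fold, exact permutation p = 0.713). A general carry-over of epidermal cells could raise basal keratinocyte genes too, so the list means were set against the basal keratinocyte mean. Relative to it, melanocyte genes were higher in Cre-positive libraries by 4.20 and stress keratinocyte genes by 3.41 (exact permutation p = 0.00117 for each). Part of this came from the basal keratinocyte mean, which was itself lower in Cre-positive libraries (difference -0.979). Without Cre-positive libraries 1 and 2 and Cre-negative library 6, the basal keratinocyte median was no longer lower (0.14). The relative differences were then 3.48 and 1.96 (exact permutation p = 0.00794 for each, the smallest possible). Neither comparison decides on carry-over, since the CD49f gate selects against basal keratinocytes and carried-over cells need not include them. The suprabasal keratinocyte mean did not differ by test (difference -0.15, exact permutation p = 0.808). Unequal numbers of Cre-positive libraries in the title series would leave no difference within series, whereas these were 3.05 (exact p = 0.00381) and 2.41 (exact p = 0.0019, the smallest possible). Carry-over of those particular cells, uptake of their RNA, or a change in these cells with the Cre genotype may account for the pattern, and none of these was tested.

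By camera with a preset correlation, type I interferon genes were higher in Cre-positive libraries, but not with an estimated correlation (adjusted p = 0.303). Unequal title series were argued against by a difference of 1.18 within series (exact p = 0.0152). Whether the pattern rests on the monocyte-rich Cre-positive libraries 1 and 2 stays open: without them the difference was 0.704 (exact p = 0.0823), the same sign but not past the threshold. The same holds for Cre-negative library 6, which had the lowest list mean: without it the difference was 0.857 (exact p = 0.053). A difference with the Cre genotype may be the source and stays open as well, and how it would arise was not tested.

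By camera with a preset correlation, MHC class II and Langerhans cell genes were lower in Cre-positive libraries. Neither list passed with an estimated correlation (adjusted p = 0.522 and 0.303) or by exact permutation of its mean (p = 0.171 and 0.0513). Unequal title series cannot be told apart from a genotype difference here: within series 51 the differences were -1.89 and -1.46, each with an exact permutation p = 0.0571, where 3 against 4 libraries allow no p below 0.0286. A difference between genotypes that itself differs between the title series may also account for it, since the MHC class II difference was lower by 2.68 in series 51 than in series 48 (-2.682, exact p = 0.0171). That p was 0.616 after adjustment over 36 lists, and series 48 has 2 Cre-negative libraries. How many Langerhans cells entered each sort was not tested.

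Other regroupings of the 13 libraries into 7 and 6 were compared with the real one, 100 in all with the real one included. For genes, 2 of 100 gave at least the 6 of the real split, so a count this high was uncommon. The highest other split gave 36, for a reason that was not tested. That split set Cre-positive libraries 4, 5 and 7 with Cre-negative libraries 1, 3, 5 and 6 against the rest. With the title series as a covariate 1 of 100, the real split, gave 19 genes. The highest other gave 13, and its group of 7 held 7 male libraries. Only 100 splits were drawn, so these counts rank the real split without excluding chance. For lists chance could not be excluded: 7 of 100 splits gave at least the real 17 (highest other 25), and 10 of 100 with the title series as a covariate (real 17, highest other 25).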

How the results depend on the processing

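The tests with title series and sex together, those that leave out Cre-positive libraries 1 and 2 jointly (with or without Cre-negative library 6) or Cre-negative library 6 with the title series in the fit, sex or library size alone for lists, marker levels within title series, and the permutation of list means were chosen after the data were seen; the other alternatives, single omissions included, were planned. The 6 called genes were called again with DESeq2 size factors and upper-quartile factors (6 each), without a filter (7, all 6 shared) and with a 2-fold minimum (6). Library size alone and robust dispersion gave 5, all shared, limma-voom with quality weights gave 7 with 4 shared, and leaving out Cre-positive libraries 1 and 2 gave 5 with 3 shared. The count moved to 3 with at least 50 counts in 6 libraries, 1 at a threshold of 0.01, 248 by the DESeq2 Wald test (105 higher, 143 lower, all 6 shared), 19 with the title series, 10 with sex and 36 with both as covariates. It was 0 in series 51 alone and 0 in series 48 alone (edgeR; 1600 and 1420 unadjusted), where fewer libraries were compared. Without Cre-positive libraries 1 and 2 and Cre-negative library 6 it was 1 (none shared), and without Cre-negative library 6 and with the title series it was 2 (1 shared). Leaving out 1 library at a time gave 0 to 13 genes: 0 without Cre-positive library 6, 2 without Cre-positive 2, Cre-negative 3 or Cre-negative 4, 3 without Cre-positive 1, 4 or 5 or Cre-negative 1, and 13 without Cre-negative 5. Cd160 kept its call only without Cre-positive 3 or Cre-negative 5 or 6, Fcgrt without these or Cre-positive 7, Myot without Cre-positive 5 or Cre-negative 5, and BC117090 lost it without Cre-positive 2, 5 or 6 or Cre-negative 1, 3, 4 or 6. Why these counts and calls moved was not tested. Rnaseh2b was not called under any setting, with log2 changes from -0.318 (3 libraries left out) to 0.096 (series 51 alone), and from -0.172 to 0.192 when 1 library was left out.

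The 17 lists past the threshold became 0 with an estimated correlation, 2 by fry, 1 by exact permutation of the list mean, 7 by permutation within title series, and 8 without Cre-positive libraries 1 and 2 and Cre-negative library 6; leaving out 1 library gave 14 to 18. Different tests of the same values give these counts, and why the 3 libraries matter was not tested. The test's direction reversed for basal keratinocyte genes without the 3 libraries (median 0.14) and for immediate early genes without Cre-negative library 6 and with the title series, where the median, already negative, was -0.561; the cause was not tested. Of the other comparisons of lists with their main value, 784 kept their side of the threshold, 68 lost the call and 4 gained it. In 110 of the 784, none a called list, the median's sign or the test's direction changed. Of 84 list members past the threshold adjusted over the list alone, 25 lost that call with the title series, 58 in at least 1 omission. For single genes 725 kept their side, with a change of sign in 16 that were not called, 71 lost the call and 51 gained it. Counts by direction stayed within 1.5 times the main count in 65 of their comparisons and left that range in 45, and 119 comparisons of marker levels kept their side, with melanocyte genes within title series the exception (adjusted exact permutation p = 0.076). No paired analysis was possible because the replicate numbers follow accession order and pair no libraries. With 7 and 6 libraries, single genes that changed 2-fold were recovered at 32% in simulated data, and at 12% with the title series. So 2-fold and smaller changes in single genes would mostly be missed at this depth and spread. In the simulation 50 genes changed at each size, up to 4 on the log2 scale, which loosens the adjusted threshold. The real fit called 6 genes, so recovery in the real data could be lower.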

Other observations

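All tests in this part were chosen after the results of the report had been seen. The title series, which no label explains, differed more than the Cre genotypes did: with the genotype in the fit, 1984 genes passed (1061 higher and 923 lower in series 51; edgeR). Exosc5, a subunit of the RNA exosome, was higher in series 51 (log2 0.998, SE 0.106, adjusted p = 0.000586; 74.1 against 37.6 CPM), as were the small nuclear RNA genes Rnu1b2 (log2 4.24) and Rnu11 (3.52) and the proteasome gene Psmb9 (0.88). Lower in series 51 were the long transcripts Ankrd11 (log2 -2.10, SE 0.22; 29.6 against 119 CPM) and Syne2 (-2.17; 48.8 against 241 CPM), the Argonaute gene Ago3 (-1.22), and the splicing genes Rbm25 (-1.60) and Srsf11 (-1.47). By list, MHC class II genes were higher in series 51 (median 1.57, adjusted p = 0.0028 by camera) and basal keratinocyte genes lower (median -1.80, adjusted p = 0.00147), each with an adjusted p = 0.996 with an estimated correlation. The summed MHC class II level differed between the series mainly in Cre-negative libraries, of which series 48 has 2 (log2 3.44, against 0.25 in Cre-positive libraries). For basal keratinocyte genes these differences were -2.69 and -2.30.

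A candidate explanation of the low Kirrel3 counts in Cre-positive libraries is a genome segment linked to a locus of the cross, which could also move neighbouring genes. Within 5 Mb lay 48 tested genes, leaving out Kirrel3 and Kirrel3os. Of these, 7 (14.6%) had an unadjusted p under 0.05, against 10.9% of genes elsewhere (odds ratio 1.39, 95% interval 0.526 to 3.14, Fisher's exact p = 0.359), and 0 passed adjustment (smallest adjusted p 0.261, edgeR). The test leaves the hypothesis open, since the interval allows both no excess and an excess of up to 3.14.

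In 49 genes every Cre-positive library lay above every Cre-negative one, and in 38 every one lay below. Chance gives 0.117% of genes, or 16.8 of those tested, for both directions together. That is a mean over splits: genes vary together across these libraries, so single splits can lie far from it, and the difference was not tested.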
